A study of Mus musculus with 4 samples.

How the data were processed

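The assay for transposase-accessible chromatin with sequencing (ATAC-seq) marks open chromatin by cutting it with the Tn5 transposase and sequencing the released fragments. Here it was run on organoids grown from crypts of the proximal small intestine of C57BL/6J mice, with 30000 cells per library. Per the labels' protocols, the 0 h organoids stayed in a medium holding CHIR99021 (a GSK3 inhibitor that activates Wnt signalling), valproic acid (a histone deacetylase inhibitor), epidermal growth factor, Noggin (a BMP antagonist) and R-spondin. The treated organoids lost CHIR99021, valproic acid and Noggin and received 100 ng/mL recombinant BMP2 for 24, 48 or 72 h. The medium therefore changed together with the BMP2. The series holds 4 libraries, 1 per time point. The 24 h and 48 h libraries were not analysed here, and the comparison is between the 0 h library and the 72 h library.

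Per the submitters' processing notes, the authors used cutadapt 1.9.1, Bowtie2 2.4.1, SAMtools 1.3.1, Picard 2.18.27, deepTools 3.5.4, MACS2 2.2.7.1 and bedtools 2.26.0 on the mm10 build; the settings of each step, such as any shift of reads for the Tn5 cut or removal of duplicates, are not given in the sources used here. The authors deposited, for each library, peak lists called at p-value thresholds of 1e-05 and 1e-10, and a list of regions named as enriched in that library. The deposited lists have no header lines; each peak's name carries the library it was called in, so peaks were called per library and not on pooled libraries. Each deposited row holds a chromosome, a start, an end and a peak name, and no score, fold enrichment, p-value or read count. Nearly all rows span 601 bp, that is, a summit with 300 bp on either side. The read depth of the libraries is therefore unknown, and no peak height could be compared. The 1e-10 lists hold a subset of the peaks of the 1e-05 lists, under the same names. The peak numbers run to 37284 at 0 h and to 42083 at 72 h, which leaves 1427 and 740 numbers with no row in the 1e-05 lists used here.

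The enriched lists were compared with the peak lists to find out what they hold. All 1276 regions of the 0 h list and all 4534 of the 72 h list were 1e-10 peaks of their own library. Of the 1275 0 h peaks at 1e-10 that no 72 h peak at 1e-05 overlapped, 1274 were in the 0 h-enriched list, and all but 1 of the 4535 such 72 h peaks were in the 72 h-enriched list. A region listed as enriched was thus called at the strict threshold in one library and, with 2 exceptions at 0 h, not even at the lenient threshold in the other. It is a difference in calling and not a measured fold.

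Regions were placed with a RefSeq gene table of GRCm38.p6, the assembly that mm10 denotes, which gives each gene's start and end but neither strand nor exons. Gene starts and gene ends could not be told apart, so "gene end" below means either boundary of a protein-coding gene, and exons and introns were not resolved. Each region's midpoint was assigned to the protein-coding gene whose body contained it or lay nearest, within 50 kb, with ties broken by the nearer gene end. The intended assignment to the nearest transcription start was replaced by this one for want of strand. Regions outside chromosomes 1 to 19, X and Y were not assigned. Coordinates are 1-based mm10 positions.

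With 1 library per time point there is no replicate, so no p-value is given and no value carries a replicate error. Shares carry exact Clopper-Pearson 95% confidence intervals, and odds ratios carry exact conditional 95% intervals; both cover counting error only. For each of 17 gene lists (10 functional groups and 7 sets of cell type markers), the number of members with at least 1 enriched region was compared with 10000 random lists of the same size. These were drawn from the 14928 protein-coding genes with at least 1 assigned peak, and matched on the number of merged 1e-05 peaks of both libraries assigned to each gene (9 bins). A list above the 97.5th percentile is described as above its random lists; 17 lists would give 0.425 such lists by chance. The percentile describes these libraries and is not a test across samples. The matched number also counts peaks found in 1 library only. A gene with peaks at 72 h only can hold no 0 h-enriched region, yet it is matched to genes that can. Low positions, such as those of enterocyte lists at 0 h or of stem cell genes at 72 h, can thus partly follow from the matching. On simulated lists of 20 genes over the 14928 genes, 2% of 200 unchanged lists passed the 97.5th percentile, and 58.5% of 200 lists whose chance of a region was raised 3-fold did. The simulated chance grew with peaks per gene, the matched quantity, and genes were drawn independently, so the 2% follows from that design. The chance was not set to the share of genes with a 72 h-enriched region. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

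The lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes are the 12 with the most 72 h-enriched regions, the 8 with the most 0 h-enriched regions, up to 4 members of each list with the most regions of its leading direction, and Id1, Id2, Id3, Smad6, Smad7, Smad4, Hnf4a, Klf4, Lgr5 and Olfm4. A few genes that this rule takes are not reported here. The coordinates printed for a named gene are mainly those of its region nearest to a gene end, in place of the nearest transcription start. Alternatives were the 1e-10 lists, a reciprocal overlap, merging within 1 kb, a window of 2 kb or genes of every biotype for gene ends, an assignment within 10 kb or to any gene within 50 kb, leaving out regions at gene ends, and thinning the 72 h set to the size of the 0 h set. After seeing the files, 4 more were added: all 1e-05 peaks of 1 library only, enriched regions with no 1e-05 peak of the other library within 1 kb, assignment by the nearest gene end, and merging of overlapping regions into sites for counts per gene and for spacing. The pooling of 5 lists into 1 set of enterocyte genes, the split of shared peaks by place, the symbol families and the spacing of regions were also not among the fixed choices. Motif searches fixed in advance were left out because no genome sequence was used here, and ranking by peak score was left out because the lists carry none.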

Results

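Chromatin accessibility was compared between mouse proximal intestinal organoids kept in a stem-cell-supporting medium (0 h) and organoids exposed to BMP2 for 72 h in a medium without CHIR99021, valproic acid and Noggin. Bone morphogenetic proteins (BMPs) signal through SMAD transcription factors and are more active toward the villus tip than in the crypt. The study asked how accessibility changes with the time of BMP exposure, as a model of the zones an enterocyte passes along the villus. Each time point is 1 library, so no difference below has a replicate check, and the read depth is unknown. At a threshold of 1e-05, 35857 peaks were called at 0 h and 41343 at 72 h, 1.15 times as many. At 1e-10 the lists held 19910 and 25040 peaks, 1.26 times as many at 72 h. The 1e-05 peaks covered 20.5 Mb of the genome at 0 h and 23.7 Mb at 72 h.

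Most accessible sites were common to both libraries. Of the 0 h peaks, 79.3% (95% interval 78.8 to 79.7, 28425 peaks) were overlapped by at least 1 bp of a 72 h peak. Of the 72 h peaks, 69.4% (68.9 to 69.8, 28682 peaks) were overlapped by a 0 h peak, which left 12661 peaks at 72 h only and 7432 at 0 h only. The authors listed 1276 regions as enriched at 0 h and 4534 as enriched at 72 h, 3.55 times as many. These were 6.41% (6.07 to 6.76) of the 0 h peaks at 1e-10 and 18.1% (17.6 to 18.6) of the 72 h peaks at 1e-10.

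The excess at 72 h lay away from gene ends. Within 1 kb of either end of a protein-coding gene, both enriched sets were of nearly equal size, with 268 regions at 0 h and 265 at 72 h. Elsewhere 4265 regions were enriched at 72 h and 1002 at 0 h, a ratio of 4.26. Regions at gene ends thus made up 21.1% (18.9 to 23.5) of the 0 h-enriched set and 5.85% (5.18 to 6.57) of the 72 h-enriched set. Among 1e-10 peaks overlapped by a peak of the other library they made up 54.3% (53.6 to 55.0) at 0 h and 50.1% (49.4 to 50.8) at 72 h. Inside genes and over 1 kb from their ends lay 38.3% of the 0 h-enriched and 48.2% of the 72 h-enriched regions. A further 12.3% and 13.5% lay over 50 kb from any protein-coding gene.

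**Figure D1:**
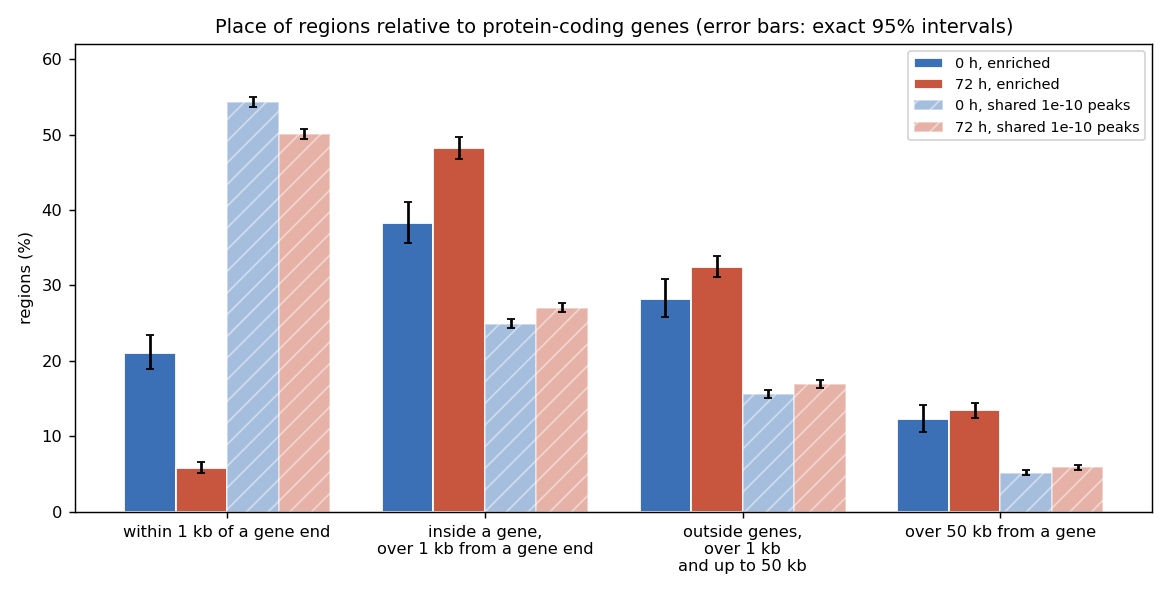
Place of regions relative to protein-coding genes, as the percentage of regions on assembled chromosomes (y axis) in 4 classes of place (x axis). Solid bars are the regions listed as enriched and hatched bars the 1e-10 peaks overlapped by a peak of the other library, with exact 95% intervals; regions at gene ends are 5.85% of the 72 h-enriched set and 21.1% of the 0 h-enriched set.

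Peaks found in both libraries showed the same split by place. Of shared 1e-05 peaks within 1 kb of a gene end, 78.4% (77.7 to 79.1) also passed 1e-10 at 0 h and 78.5% (77.8 to 79.2) at 72 h. Of shared peaks farther away, 55.0% (54.2 to 55.8) passed at 0 h and 65.7% (65.0 to 66.5) at 72 h. The odds ratio of passing at 72 h against 0 h was 1.01 (0.95 to 1.07) at gene ends and 1.57 (1.50 to 1.64) elsewhere, a split made after the data were examined. The intervals treat the peaks of the 2 libraries as separate sets, without pairing the calls of each shared site.

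Regions enriched at 72 h were assigned to 2842 genes, 19.0% of the 14928 genes with a peak, and 0 h-enriched regions to 1017 genes, 6.81%. Among the genes with the most 72 h-enriched regions were Mgam, Adgrl3 and Lingo2 with 7 each, and Dab1, Elmo1, Mecom and Slc34a2 with 6 each. Arhgap26, Camk1d, Camk2d and 1700057G04Rik followed with 5 each, taken in alphabetical order from a larger tie that also holds Hnf4g. Some of these regions overlap: merged into sites, Mgam had 6, Elmo1, Mecom and Slc34a2 had 5 each, and Arhgap26 and Camk2d had 4 each. Several of these genes are very long: Lingo2 spans 1255 kb, Dab1 1125 kb and Adgrl3 809 kb, whereas the median gene with a peak spans 23.7 kb. Mgam and Slc34a2 are shorter, at 140.3 and 22.3 kb. Mgam encodes maltase-glucoamylase, a brush border enzyme of starch digestion, and Slc34a2 a sodium-phosphate cotransporter. All 6 Slc34a2 regions lay outside the gene, the nearest at chromosome 5, 53074455 to 53075055, 3.09 kb from a gene end. At 219 genes there were 3 or more 72 h-enriched regions, against 8 genes with 3 or more 0 h-enriched regions. Those 8 were Tbc1d1 with 4 and BC107364, Ccdc192, Dnah2, Kif12, Myh9, Tamm41 and Tekt5 with 3 each. With overlapping regions merged, a count chosen after seeing the data, 208 genes at 72 h and 3 at 0 h (Tbc1d1, Ccdc192 and Myh9) had 3 or more sites. At Kif12, which encodes a kinesin, the 3 regions formed 2 sites, both within 1 kb of a gene end.

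Enterocyte genes carried 72 h-enriched regions far more often than 0 h-enriched ones. Pooled after the data were examined, the 5 lists of enterocyte genes (3 villus zones, brush border and lipid handling) hold 91 different genes, of which 85 had a peak. At 72 h, 53 of the 85 (62.4%, 51.2 to 72.6) had an enriched region, against a mean of 31.0 (95% range 23 to 39) in matched random lists. The highest of 10000 such lists reached 46. At 0 h, 7 of the 85 (8.24%, 3.38 to 16.2) had one, against a random mean of 10.7 (5 to 17). Because the matching counts peaks of both libraries, the lower number at 0 h can partly follow from it. The odds that an enriched region lay at one of these genes were 4.05 times as high (1.89 to 10.4) for the 72 h set as for the 0 h set, with 99 of 4534 regions against 7 of 1276. The 99 regions lay at 53 genes and are not independent, so this interval is too narrow.

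Among mid-villus genes, 12 of 17 had a 72 h-enriched region and none a 0 h-enriched one, against means in random lists of 6.38 at 72 h (3 to 10; percentile 99.8) and 2.16 at 0 h (0 to 5; percentile 4.71). Slc5a1 (the apical sodium-glucose cotransporter), Slc15a1 (the apical peptide transporter) and Slc7a7 (a basolateral amino acid transporter subunit) had 3 regions each. Fabp1, which encodes a fatty acid binding protein, had 2 among 4 peaks at 72 h, and no peak at 0 h. It could thus hold no 0 h-enriched region, although it was matched to genes that could. The Slc5a1 regions all lay outside the gene on chromosome 5, the nearest at 33092261 to 33092861, 11.7 kb from a gene end. The Slc7a7 regions all lay inside the gene on chromosome 14, between 54383120 and 54402233. The nearest Fabp1 region was at chromosome 6, 71184891 to 71185491, 14.7 kb outside the gene. Of villus-bottom genes, 6 of 11 with a peak had a 72 h-enriched region and none a 0 h-enriched one (random means 2.35, 0 to 5, percentile 99.5 at 72 h, and 0.785, 0 to 3, percentile 22.0 at 0 h). They included Il18 (an epithelial cytokine; 3 regions and no 0 h peak), Nlrp6 (an innate immune sensor; 2), Ccl25 (a small intestinal chemokine; 1) and Dmbt1 (a mucosal scavenger protein; 1). Of villus-tip genes, 10 of 19 had a 72 h-enriched region (random mean 6.73, 3 to 10; percentile 95.9), which was not above their random lists, and 3 had a 0 h-enriched one (Egfr, Klf4 and Slc28a1; percentile 68.5). Krt20 (a keratin of differentiated enterocytes) and Xdh (xanthine dehydrogenase) had 3 regions each, Atf3 had 2 and Ada (adenosine deaminase) 1. The shares of the 3 zones, whose difference was not tested, were 70.6% (44.0 to 89.7) for mid-villus, 54.5% (23.4 to 83.3) for villus-bottom and 52.6% (28.9 to 75.6) for villus-tip genes.

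**Figure D2:**
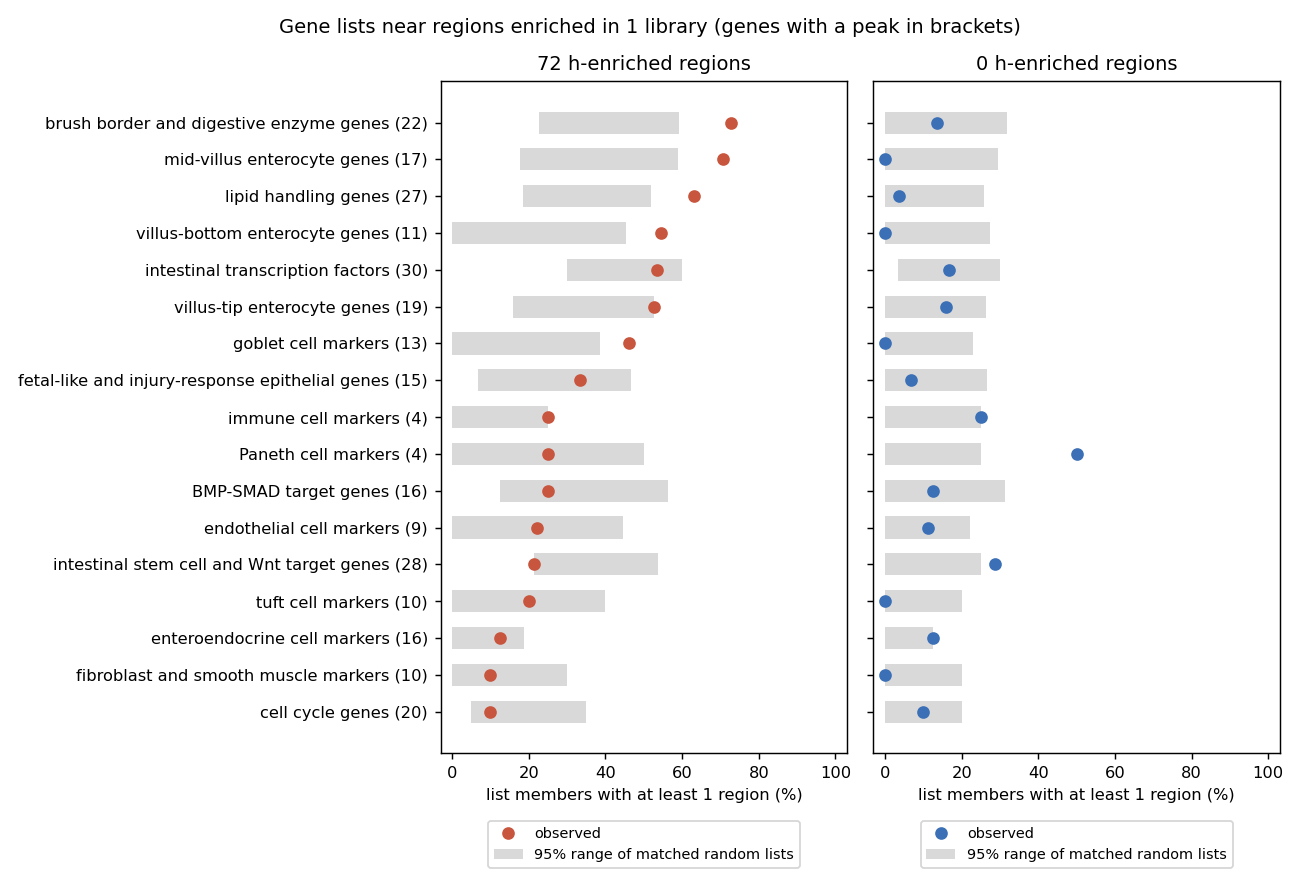
Percentage of list members with at least 1 enriched region (x axis) for 17 gene lists (rows; genes with a peak in brackets), for the 72 h-enriched (left) and 0 h-enriched (right) sets. Points are the observed shares and grey bars the 95% range of 10000 random lists matched on peaks per gene; 5 lists lie above percentile 97.5 at 72 h and 2 at 0 h.

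Brush border and digestive enzyme genes had 72 h-enriched regions at 16 of 22 members with a peak (random mean 9.17, 5 to 13; percentile 99.95) and 0 h-enriched regions at 3 (Dpp4, Eps8 and Eps8l3; percentile 46.2). Besides Mgam, the leading members were Alpi (intestinal alkaline phosphatase), Dpp4 (a peptidase) and Mep1b (a meprin protease subunit), with 3 regions each. Alpi had 5 peaks at 72 h and none at 0 h. The nearest region lay across the gene end on chromosome 1, at 87101267 to 87101867, and the farthest was centred 3.52 kb outside the gene. This list was not above its random lists when all 1e-05 peaks of 1 library only were used (percentile 91.2), a definition chosen after seeing the data. Lipid handling genes had 72 h-enriched regions at 17 of 27 members (random mean 9.42, 5 to 14; percentile 99.9) and a 0 h-enriched region at 1, Acsl5 (percentile 8.49). Ppara, the nuclear receptor of fatty acid oxidation, had 4 regions, all inside the gene on chromosome 15. Scarb1 (a lipoprotein receptor) had 3, and Fabp1 and Gpat3 (an acyltransferase of triglyceride synthesis) had 2 each. The mid-villus and lipid lists share members with other lists, 8 of 17 and 9 of 28.

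Of 28 intestinal stem cell and Wnt target genes, 8 had a 0 h-enriched region (random mean 3.36, 0 to 7; percentile 99.2), and 6 had a 72 h-enriched one (random mean 10.4, 6 to 15; percentile 3.56). Ascl2, a transcription factor of crypt base stem cells, had 2 regions at 0 h: chromosome 7, 142967999 to 142968599 inside the gene, and 142969131 to 142969731 at its end. Ephb2 and Ephb3, receptors that position cells in the crypt, and Lrig1 (a negative regulator of growth factor receptors) had 1 each. Ephb2 also had 1 at 72 h. Lgr5, the R-spondin receptor of stem cells, had 1 region at 72 h, 37.3 kb outside the gene, and none at 0 h. Olfm4 had none in either set. The position above random lists at 0 h ended when regions at gene ends were left out (6 members, percentile 96.7) and when a 1 kb gap to any 72 h peak was required (4 members, percentile 77.9). It was kept within 10 kb (7 members, percentile 99.2), with every gene within 50 kb (9, 99.0), by the nearest gene end (8, 99.1) and with 1e-05 peaks of 1 library only (19, 97.6). In the same order, these 6 alternatives gave 6, 4, 3, 10, 6 and 15 members at 72 h, at percentiles 6.07, 0.88, 1.18, 39.6, 4.33 and 1.57. Thinning the 72 h set to the size of the 0 h set left a mean of 1.65 members at 72 h. The low positions at 72 h can partly follow from matching on the peaks of both libraries.

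BMP-SMAD target genes did not stand out in either set. This count cannot register a gain at a site already called as a peak at 0 h. Of 16 members with a peak, 4 had a 72 h-enriched region (random mean 5.56, 2 to 9; percentile 19.0) and 2 a 0 h-enriched one, Msx2 and Pmepa1 (percentile 57.4). The 4 were Id3, Smad7, Skil and Pmepa1 with 1 each. Under 6 alternatives, the 72 h percentile of the list ran from 3.5 (a 1 kb gap to any 0 h peak) to 40.3 (every gene within 50 kb). The Id3 region lay at chromosome 4, 136146667 to 136147267, 1.58 kb outside the gene, and the Smad7 region at chromosome 18, 75356910 to 75357510, 10.2 kb outside. Id1, Id2 and Smad6 had none in either set, nor did Smad4, which belongs to the list of transcription factors and not to this one. Each had peaks in both libraries: 5 and 5 at Id1, 5 and 7 at Id2, 8 and 10 at Smad6, and 2 and 4 at Smad4, at 0 h and 72 h.

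Of 30 intestinal transcription factor genes, 16 had a 72 h-enriched region (random mean 13.6, 9 to 18; percentile 84.2) and 5 a 0 h-enriched one, among them Foxa2, Klf4, Pparg and Vdr (percentile 53.9). The list as a whole thus lay within its random lists. Hnf4g had 5 regions, all inside the gene on chromosome 3, with 12 peaks at 72 h and 5 at 0 h. Its paralogue Hnf4a, a regulator of enterocyte differentiation, had 1, 2.55 kb outside the gene. Gata4 had 2. Klf4 had 1 region in each set: at 72 h on chromosome 4 at 55493090 to 55493690, 33.7 kb outside the gene, and at 0 h inside the gene at 55530095 to 55530695.

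Markers of other cell types were examined because organoids hold several lineages. Goblet cell markers had 72 h-enriched regions at 6 of 13 members with a peak (random mean 2.71, 0 to 5; percentile 98.6) and 0 h-enriched regions at none (random mean 0.920, 0 to 3; percentile 18.9). Agr2 had 2 regions, and Muc2 (the main secreted mucin), Clca1 and Creb3l4 had 1 each. The goblet list fell within its random lists when every gene within 50 kb was counted (percentile 66.1) and with 1e-05 peaks of 1 library only (percentile 75.8). Paneth cell markers had peaks at 4 of 11 members; Itln1 and Nupr1 had a 0 h-enriched region (percentile 98.9), a position that rests on those 2 genes and ended when gene ends were left out (percentile 88.3) or every gene within 50 kb was counted (percentile 93.0). At 72 h, 1 Paneth marker, Wnt3, had a region (percentile 58.8). Enteroendocrine markers had 2 of 16 members with a region in each set, Gip and Sct at 72 h (random mean 1.07, 0 to 3) and Isl1 and Lmx1a at 0 h (random mean 0.493, 0 to 2). With 1e-05 peaks of 1 library only, this list lay above its random lists at both times, with 8 members at 72 h and 6 at 0 h. Tuft cell markers had Alox5ap and Sh2d6 at 72 h, 2 of 10 (percentile 72.7), and none at 0 h (percentile 29.3). Cell cycle genes had 2 of 20 in each set, Cdk1 and Mcm6 at 72 h (percentile 18.2) and Aurkb and Ccne1 at 0 h (percentile 76.6). Fetal-like and injury-response genes had 5 of 15 at 72 h (percentile 73.2), with 2 regions each at Areg and Ereg and 1 each at Anxa1, Krt19 and Krt7, and 1 at 0 h (S100a6; percentile 42.9). Fibroblast and smooth muscle markers had 1 of 10 at 72 h (Dcn), immune markers 1 of 4 (Csf1r) and endothelial markers 2 of 9 (Tek and Pecam1), at percentiles 48.1, 87.1 and 55.9. At 0 h the fibroblast list had none (percentile 31.7), the immune list 1 (Spi1; percentile 93.8) and the endothelial list 1 (Tek; percentile 69.3). With 1e-05 peaks of 1 library only, 6 of the 9 endothelial markers had a 0 h region (percentile 99.0). Krt7, Wnt3 and the genes named for 0 h-enriched regions in all lists but the stem cell and Paneth ones were named after their values were seen, except Dpp4, Klf4, Pmepa1 and Tek.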

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

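In this part, the tests of the peak numbering, of calling power, of the pooled enterocyte genes and of the Y chromosome were chosen after the result was seen; the count of libraries that vary BMP2 and medium separately was not.

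On the Y chromosome, a part of the data that no comparison above treats by itself, the 72 h list at 1e-05 held 100 peaks between 50 and 90 Mb, of which 18 are listed as enriched, and the 0 h list held none, although beyond 90 Mb it held 32, beside 26 at 72 h. Loss of 0 h peaks from the deposited list is argued against by its numbering, which skips 3 numbers between its first and last Y peak. Absence of the Y chromosome from the 0 h cells is excluded as well, since 11 0 h peaks lay in the first 3.5 Mb of Y, beside 13 at 72 h. A repeated sequence unit called at many copies is a candidate explanation: 12 of the 100 peaks fell in 1 bin of 100 bp in distance to the nearest gene (22.2 to 22.3 kb), and the fullest bin in 1000 random placements held 8. Why peaks were called there in the 72 h library and not in the 0 h library was not tested.

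The 3.55-fold excess of 72 h-enriched over 0 h-enriched regions may reflect how well peaks were called. Peaks missing from the numbering cannot account for it: 420 of the 72 h-enriched regions lie where the 0 h numbering skips, fewer than the excess of 3258. For higher calling power in the 72 h library at all sites alike, shared peaks were compared by place. Their odds of passing 1e-10 differed by a ratio of 1.01 (0.95 to 1.07) at gene ends and 1.57 (1.50 to 1.64) away from them. An equal gain in odds at both places is argued against. A uniform gain in power need not be equal in odds, because peaks at gene ends passed more often already at 0 h (78.4%, against 55.0%). That explanation therefore stays open. At gene ends taken alone a small gain in power cannot be told apart from none (78.5% passing at 72 h and 78.4% at 0 h), because the intervals overlap. These comparisons did not pair the 0 h and 72 h calls of each shared site. Higher calling power away from gene ends stays open: shared peaks there passed more often at 72 h (65.7%, against 55.0% at 0 h; 71.6% against 65.6% over all places), which a biological gain would also give, and depth and replicates are missing.

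Whether the enterocyte genes near 72 h-enriched regions follow from calling power alone stays open. The 72 h-enriched regions had 2.02 times the odds (1.49 to 2.72) of lying at one of these 91 genes. The reference was the weaker 72 h peaks absent at 0 h. This ratio cannot decide, because the 2 sets differ in peak strength by construction. Its interval is also too narrow, since several regions lay at the same gene. More peaks per gene alone is argued against, since 0 of 10000 lists matched on peaks per gene reached the 53 members. Those lists drew genes singly, whereas some members, such as Apoa1 and Apoa4, are neighbours, so their range is too narrow. They were also not matched on place. BMP2 itself cannot be told apart from the removal of CHIR99021, valproic acid and Noggin, because 0 libraries vary them separately. A larger share of enterocytes in the culture and a change within each cell also both stay open, untested.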

How the results depend on the processing

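Among alternative values of the leading results, 51 stayed within their interval, or within 1.5 times for a count, and 30 moved; 71 of 174 other list counts moved. The cause of each move was not tested, except where a setting shrinks or widens the set by construction. At 1e-10 the lists held 19910 peaks at 0 h and 25040 at 72 h. The overlapped share of 0 h peaks was 82.8% at 1e-10, 75.3% with a reciprocal overlap and 93.6% for 1e-10 peaks against the 1e-05 peaks of the other library; that of 72 h peaks was 67.6%, 65.6% and 81.9%. With all 1e-05 peaks of 1 library only, which drops the strict threshold, 7432 regions were enriched at 0 h and 12661 at 72 h. The share at gene ends, for 0 h and 72 h, was 27.2% and 10.7% within 2 kb, 30.1% and 10.5% with genes of every biotype, and 17.6% and 6.96% for 1e-05 peaks of 1 library only. In counts, this last setting gave 1300 regions at gene ends at 0 h and 879 at 72 h, so the near equality of the 2 enriched sets there was not kept. The number of lists above their random lists at 0 h (2 of 17) was 1 with any gene within 50 kb, 0 without gene ends, 4 with 1e-05 peaks of 1 library only and 1 with a 1 kb gap; at 72 h it was 4 or 5 in each. Genes with 3 or more 0 h-enriched regions (8) became 3 with overlapping regions merged. Stem cell members at 0 h (8) became 19 with 1e-05 peaks of 1 library only and 4 with a 1 kb gap. Paneth members at 0 h (2) became 1 without gene ends and 4 with 1e-05 peaks of 1 library only. Thinning the 72 h set to 1276 regions gave means over 100 draws of 2.29 villus-bottom, 5.45 mid-villus, 7.42 brush border, 6.33 lipid handling and 2.06 goblet members. The mid-villus, villus-bottom and lipid lists lay above their random lists at 72 h under 6 of 6 alternatives that change the set or the assignment, brush border under 5 and goblet under 4. Requiring overlap with an own 1e-10 peak removed no region and so tested nothing. The motif searches and the ranking by score were not run. No paired analysis was possible because each time point has 1 library. Depth is also a limit: without read counts, a site absent from one list is not shown to be closed.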

Other observations

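All of the tests in this part were chosen after the data were seen. Beyond the lists fixed in advance, gene families were grouped by the letters of their symbols, and 96 families with at least 15 genes with a peak were compared with matched random lists. Above the 97.5th percentile lay 8 families at 72 h and 3 at 0 h, against 2.4 expected by chance in each. Cytochrome P450 genes (Cyp) had a 72 h-enriched region at 22 of 61 members, against a random mean of 10.2 (5 to 16), with 0 of 10000 random lists reaching it. Carboxylesterases (Ces) had 9 of 15 (random mean 2.57, 0 to 5), UDP-glucuronosyltransferases (Ugt) 7 of 16 (2.50, 0 to 5) and aldo-keto reductases (Akr) 7 of 15 (3.04, 0 to 6). Solute carriers (Slc) had 91 of 308 (74.6, 62 to 88) and transporters of the Mfsd family 8 of 21 (3.49, 1 to 7). The Slc members include mid-villus genes already reported above, among them Slc15a1, Slc5a1 and Slc7a7, so this family is not separate from that list. Olfactory receptor genes (Olfr) had 15 of 70 (4.09, 1 to 8). Genes whose symbols start with Cd and a digit, grouped by letters alone and of unlike function, had 16 of 51 (8.46, 4 to 13). Several of these families sit in clusters of neighbouring genes, so their members are not independent and the ranges are too narrow. The random lists for families at both times were matched on peaks per gene and not on place. Families were not checked with regions at gene ends left out, so an effect of place on these counts stays open.

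At 0 h, the Sox family of developmental transcription factors had an enriched region at 6 of 16 members (random mean 1.46, 0 to 4; 12 of 10000 random lists reached it): Sox1, Sox4, Sox7, Sox11, Sox21 and Sox30. The other families above the line at 0 h were Cdc, with 6 of 29 members (2.19, 0 to 5), and Ly, with 3 of 17 (0.818, 0 to 3). Both are grouped by letters alone, and Ly lay barely above the line (percentile 97.53). The 3 families at 0 h are close in number to the 2.4 expected by chance. Regions enriched at 72 h lay closer together than drawn ones. With overlapping 1e-10 peaks merged into sites, 15.0% of 4447 enriched sites had another within 10 kb, against 12.5% on average (95% range 11.3 to 13.7) in 1000 draws of 72 h sites matched on lying at gene ends. Without merging the share was 18.1% against 14.9% (13.5 to 16.2). At 0 h, with merging, 48 of 1261 enriched sites (3.81%) had a neighbour, against 44.2 on average, and 350 of the 1000 draws reached 48.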
